A study of Mus musculus with 6 samples.

How the data were processed

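Soft palate tissue of mouse embryos at E14.0 was profiled by RNA sequencing on an Illumina NextSeq 500, per the labels, in 3 control libraries (replicates 1, 2 and 3) and 3 mutant libraries (replicates 5, 6 and 7). Per the series' design text every RNA sample had an integrity number above 9, and per the labels' protocols RNA was isolated with a column kit and libraries were made at a core facility; the library kit, its strand and any selection of RNA are not given in the sources used here. Reads were aligned with STAR to mm10, per the submitters' processing notes, which give no version. The deposited tables hold values in CPM, reads per gene scaled to a common library total, with a constant of 0.0001 added to each, as found from the values; after its removal each library summed to the same total. The counting step and the annotation are not given in the sources used here. One table holds 21938 genes and the other a filtered list of 2432 genes with identical values. Samples are rows, matched to the labels by name, and no column of per-sample values was left unused (0 columns).

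No table of counts was used here, so no count model was fitted. The step between low values gave the value of 1 read in each library and from it the counted reads, 10018701 to 15089455 per library. Within 0.02 of a read, 63.5 to 67.4% of low values were whole reads, so some reads were counted in parts and whole reads were not recovered. Intervals and floors from depth cover counting error only, since no molecular identifiers are named.

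CPM values were taken as log2(CPM + 1), and mutant was compared with control by limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance and Benjamini-Hochberg adjustment over all 21938 genes, with no filter on low values; a threshold of 0.05 was set on the adjusted p. A log2 change is on the log2(CPM + 1) scale, which understates the change of low genes. The design had expected tables of the authors' comparisons and named this test for the case that values per sample were found. Replicate numbers are not shared between the groups and no batch is given, so no block or covariate was used. The sample names were checked for copies: no pair of libraries correlated above 0.988.

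Before the data were examined, 34 gene lists were fixed for the tissue and the question, as well as the rule for the genes named. The rule names 11 fixed genes (Ctnnb1, Osr2, Axin2, Lef1, Ttll3, Gli1, Ptch1, Myod1, Myog, Runx2 and Sox9), the 8 largest rises and 8 largest falls among called genes at or above the median level of 11.2 CPM, the 5 smallest p, and up to 4 members with the smallest p of each list past the threshold or with at least 3 called genes, passing over genes known only by a clone or model identifier and pseudogenes. The values of some list members are not reported here. The 33 lists with at least 5 measured genes were tested with camera (limma) at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the libraries, under which no list passed. Counts of called genes were compared with Fisher's exact test, two-sided, which takes genes as independent. A count adjusted over the list alone applies Benjamini-Hochberg to the list's members only. The lists cover canonical Wnt targets, Wnt ligands and receptors, cadherins and catenins, tubulin glycylation and glutamylation, intraflagellar transport, the transition zone, motile cilia, Hedgehog, palatal mesenchyme, skeletal muscle, osteogenic, chondrogenic, tendon, epithelial, respiratory and nasal, pituitary and brain, endothelial, pericyte and smooth muscle, erythroid, macrophage, Schwann cell, neuronal, melanocyte, cell cycle, p53, BMP and TGF-beta, FGF, retinoic acid, Notch, fibroblast matrix, stress, hypoxia and glycolysis, mitochondrial and sex-linked genes.

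Gene positions, strands, lengths and the place of non-coding genes were taken from GENCODE vM21 on GRCm38, the assembly that mm10 names, by gene symbol; 21422 of the genes (97.6%) matched, and 51 matched more than 1 gene and were left out of tests that use position. Bootstrap intervals over genes used 2000 draws. Alternatives fixed before the data were examined changed the threshold, added fold limits, restricted the genes tested by level, used a pseudocount of 0.1, scaled the libraries differently, left out each replicate and changed the list tests. Having no filter was itself the main setting. Others were added after the data were seen: sex read from Xist (above 100 CPM) as a covariate, voom weights on reads estimated from CPM and depth for genes with a mean of at least 10, a prior variance without trend or with robust fitting, and fry for the lists. The test was checked on simulated libraries at these depths with 200 of 21938 genes changed and a between-library coefficient of variation of 15%: for mutant against control it found 17.9% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 3-fold, with 0% false calls, and it called the 1 changed list and 0 of 40 unchanged lists. The simulated genes varied independently of each other, unlike genes in tissue. They all had the same coefficient of variation, and the changed genes were drawn from those at or above the median level. The shares found may therefore be too high for these data, where 0 of 55 motile cilium genes passed at a median log2 change of 0.99. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.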

Results

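RNA of the soft palate, the posterior muscular part of the palate, was sequenced from mouse embryos at E14.0. The libraries came from 3 controls carrying floxed alleles of β-catenin and 3 mutants in which Osr2-Cre, a recombinase driven from a gene expressed in palatal mesenchyme, deletes β-catenin. The labels call the genotype of the controls wild type in one field and floxed in another, and the floxed description is used here. The series title asks how canonical Wnt signalling acts on soft palate development through the homeostasis of cilia, so genes of the Wnt pathway, of cilia and of the cell types of the palate were examined. The deposited table held CPM values, reads per gene scaled to the library total, of 21938 genes. The step between low values put the counted reads at about 12502875, 10018701 and 12842767 in control replicates 1, 2 and 3, and at 12272880, 13153589 and 15089455 in mutant replicates 5, 6 and 7. A gene with no read in a library could lie at up to 0.199 to 0.299 CPM, the value of 3 reads, for counting error alone. The first principal component, 39.5% of the variance, parted the groups, and Pearson correlations across genes were 0.981 to 0.986 within controls, 0.981 to 0.988 within mutants and 0.971 to 0.981 between groups. Whether each library came from 1 embryo or a pool is not stated in the labels, so the p-values measure the spread between these libraries.

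The targeted gene was examined first. Ctnnb1, which encodes β-catenin (chromosome 9, 120929216 to 120960507, GRCm38), measured 698.5, 784.5 and 671.5 CPM in the controls and 584.6, 633.4 and 581.6 CPM in the mutants. The mean went from 718 ± 59.0 to 600 ± 29.1 CPM (SD, n = 3 each), a log2 change of -0.26 ± 0.10 (SE) with an adjusted p of 0.183 in limma, so it did not pass the threshold although the groups did not overlap. Groups that do not overlap were found for 27.8% of all genes, where chance alone gives 10%. The 95% interval of the fold was 0.717 to 0.976, not adjusted for the number of genes. The value covers the whole gene in a piece of tissue that also holds cells without Cre, and reads outside the deleted exons still count. Osr2, whose locus drives the Cre (chromosome 15, 35296098 to 35303305, GRCm38), fell from 46.9 ± 11.2 to 16.1 ± 3.22 CPM (log2 change -1.47 ± 0.20, adjusted p = 0.0285). The Cre allele is inserted at Osr2 and only the mutants are described as carrying it. An effect of the altered allele and one of β-catenin loss on Osr2 cannot be told apart here.

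Among all genes, 105 changed between mutant and control at an adjusted p below 0.05, 43 higher and 62 lower in the mutant. At an unadjusted p below 0.05 in limma there were 4702 of the 21938 genes, against 1097 expected by chance. A list's count at that cut, given below, has to be read against this share of the table. Skeletal muscle genes were among the 62 that fell. Pax7, a regulator of muscle progenitors, fell from 13.3 ± 1.59 to 4.25 ± 0.41 CPM (SD, n = 3 each; log2 change -1.44 ± 0.16, adjusted p = 0.0271), and Myog, which drives myoblast differentiation, from 64.1 ± 15.3 to 21.6 ± 1.42 CPM (-1.50 ± 0.17, adjusted p = 0.0276). Fgfr4, a receptor tyrosine kinase of the FGF family, fell from 15.9 ± 1.87 to 5.24 ± 0.19 CPM and Vgll2, a cofactor of TEAD factors found in muscle, from 15.2 ± 1.19 to 5.05 ± 0.63 CPM. Both had an adjusted p of 0.0271. The other large falls were Adcy8, an adenylyl cyclase and the largest by ratio among called genes at or above the median level (11.8 to 3.25 CPM), Xirp1, an actin-binding protein of striated muscle (13.1 to 4.25 CPM) and Tmem132c (44.1 to 14.4 CPM). Zyx, a focal adhesion protein (85.8 ± 5.92 to 47.3 ± 1.84 CPM), Ablim3, an actin-binding protein (46.2 to 17.4 CPM), and Ank1, an ankyrin of the membrane skeleton (45.6 to 18.5 CPM), had, with Fgfr4 and Vgll2, the smallest p once pseudogenes and genes known only by a clone or model identifier were passed over.

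The genes that rose were a mixed group of coding genes and non-coding transcripts. Those named here lay at or above the median level, with pseudogenes and genes known only by a clone or model identifier passed over. Within these limits the coding genes with the largest rises were Ccdc162 (5.98 ± 1.57 to 15.6 ± 2.02 CPM, adjusted p = 0.0390), Sgms2, a sphingomyelin synthase (27.0 ± 2.76 to 68.6 ± 21.7 CPM, adjusted p = 0.0387), Ccdc18 (27.2 to 59.3 CPM) and Ccdc191 (15.3 to 28.0 CPM). The non-coding transcripts Kcnq1ot1, the antisense RNA of the Kcnq1 imprinted domain (728 ± 62.3 to 1396 ± 141 CPM, log2 change 0.94 ± 0.12, adjusted p = 0.0276), Mir99ahg (50.7 to 102.3 CPM), Ppnr (18.6 to 40.9 CPM) and Egfros (7.56 to 16.1 CPM) rose as well. Ppnr lies inside an intron of Tcf7l2 on the same strand and Egfros inside an intron of Egfr on the opposite strand, and Kcnq1ot1 overlaps a coding gene. Whether counting used strand is not given in the sources used here, so their reads cannot be told from those of the overlapping genes.

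The count of calls moved with single libraries. In limma, no gene passed with control replicate 1, control replicate 3, mutant replicate 5 or mutant replicate 6 left out (3806, 3878, 4100 and 4023 genes at an unadjusted p below 0.05). Without mutant replicate 7, 2 passed, 0 of them among the 105, and without control replicate 2, 452 passed, all 105 among them. None passed with a prior variance that has no trend or with sex as a covariate. All 105 kept their direction in each of these fits, but they were chosen on these same libraries, so this is not independent evidence. Of the 111 genes that the naming rule gave, 18 moved in log2 change by over 1.5 times or turned with 1 library left out, none of them called. Scaling the libraries to the median of genes above the median level gave 130 genes, 66 higher and 64 lower, against 43 and 62.

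**Figure D1:**
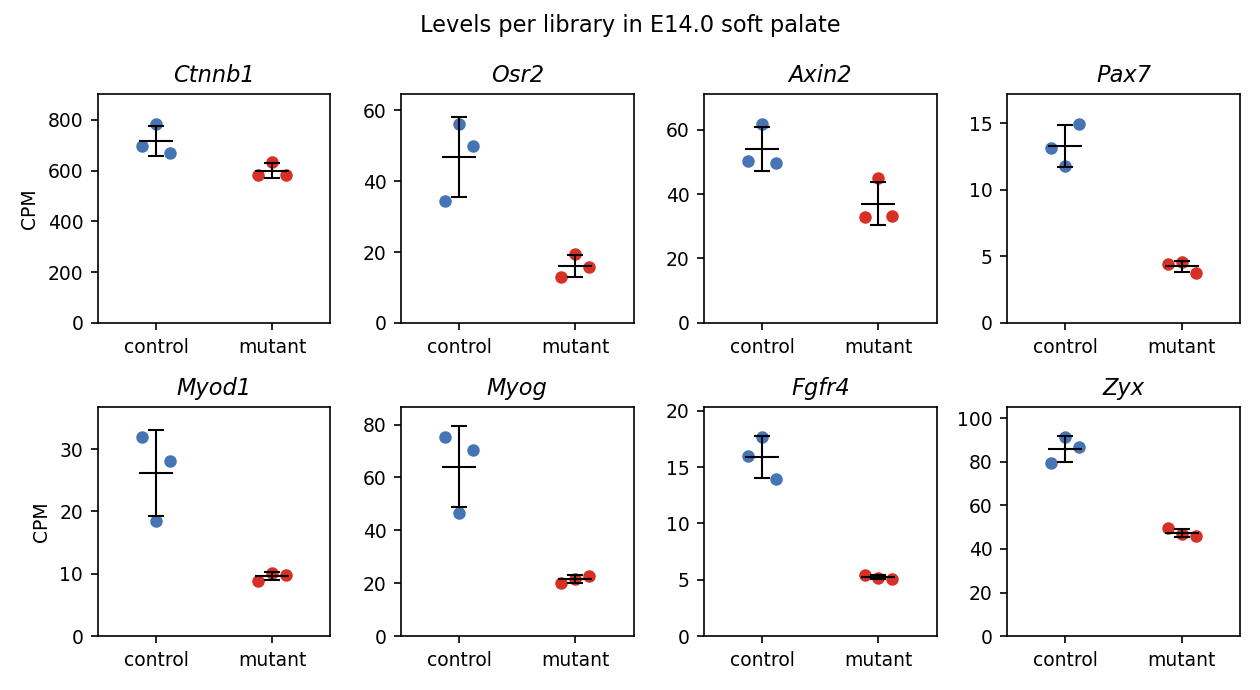
Levels in CPM of 8 genes in each library of control (blue) and mutant (red) soft palate, with the group mean and SD as black bars (n = 3 each) and every axis starting at 0. Osr2, Pax7, Myod1, Myog, Fgfr4 and Zyx fell in the mutant, whereas Ctnnb1 and Axin2 did not pass the threshold (adjusted p = 0.183 and 0.104).

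Skeletal muscle genes fell as a group. Of the 43 measured members of the list, 12 fell and 0 rose over all genes tested, and 41 fell adjusted over the list alone, with a median log2 change of -1.08. Regulators and contractile genes were both among them. Myod1, a myogenic regulator, fell from 26.2 ± 6.93 to 9.63 ± 0.67 CPM (log2 change -1.32 ± 0.20, adjusted p = 0.0352), Tnni1, the slow troponin I, from 73.5 ± 17.8 to 27.9 ± 1.23 CPM, and Ryr1, the calcium release channel of skeletal muscle, from 138.9 ± 15.4 to 75.0 ± 5.09 CPM. The 2 members that did not pass over the list alone were Pax3 (7.27 and 8.49 CPM in control and mutant) and Mef2c (265.3 and 177.7 CPM), named after their values were seen. The list ranked below all other genes in camera with an adjusted p of 2.29e-33 at a preset correlation, and an adjusted p = 0.46 with an estimated correlation. Called genes were more frequent in it than in the table (Fisher's exact test, two-sided, adjusted p = 3.38e-17). That test takes genes as independent, whereas the estimated correlation between the list's members was 0.717. Its p therefore does not measure the spread between libraries.

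The pericyte and smooth muscle list ranked lower too. Of its 13 measured members, 2 fell over all genes tested and 4 adjusted over the list alone (median log2 change -0.28). Acta2, smooth muscle actin, fell from 156.9 ± 43.9 to 56.8 ± 5.42 CPM (adjusted p = 0.0296) and Des, desmin, from 143.8 ± 36.1 to 55.9 ± 11.9 CPM (adjusted p = 0.0362). Des is also a member of the skeletal muscle list, and Acta2 is known to be made by embryonic skeletal muscle. Myh11, the smooth muscle myosin, measured 10.6 and 4.55 CPM (adjusted p = 0.133) and Tagln 29.2 and 17.6 CPM (adjusted p = 0.144). Its camera adjusted p was 0.000261, and the adjusted p = 0.46 with an estimated correlation. The Fisher test on called genes, which rests on these 2 genes, gave an adjusted p of 0.0282. It was 0.547 and 0.860 with calls at an FDR of 0.1 and at an unadjusted p below 0.05.

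Cilium genes went the other way. None of the 55 measured genes of the motile cilium list passed over all genes tested, 45 had an unadjusted p below 0.05 in limma, and 42 were higher adjusted over the list alone, with a median log2 change of 0.99. Dnah2, an axonemal dynein heavy chain, measured 17.3 ± 4.54 CPM in control and 37.6 ± 6.84 CPM in mutant (log2 change 1.09 ± 0.20, adjusted p = 0.0570), Spag17, of the central pair, 14.99 and 32.2 CPM (adjusted p = 0.0571), Spag6l 6.23 and 15.1 CPM, and Ccdc40 25.2 and 50.4 CPM. Of its regulators, named after their values were seen, Foxj1 (67.0 ± 36.0 and 83.7 CPM, adjusted p = 0.472), Rfx2 (12.1 and 15.4 CPM, adjusted p = 0.340) and Ccno (20.9 and 32.4 CPM, adjusted p = 0.288) did not pass over the list alone. Rfx3 (59.2 and 76.7 CPM, adjusted p = 0.0833) and Mcidas (16.2 and 27.1 CPM, adjusted p = 0.204) did. The list ranked above other genes in camera (adjusted p = 1.59e-18, and adjusted p = 0.51 with an estimated correlation).

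Lists of ciliary transport and of the ciliary transition zone and basal body ranked higher as well. These lists do not tell primary from motile cilia, and they moved the same way as the motile cilium list. In the list of intraflagellar transport and the BBSome, the carriers of ciliary cargo, 1 of 44 measured genes rose over all genes tested and 10 were higher adjusted over the list alone, with none lower and a median log2 change of 0.19. Wdr60, an intermediate chain of the dynein of retrograde transport, rose from 48.1 ± 0.75 to 79.6 ± 12.03 CPM (log2 change 0.70 ± 0.12, adjusted p = 0.0462), while Ift88 measured 40.1 and 56.7 CPM (adjusted p = 0.0686), Dync2h1 118.2 and 180.9 CPM (adjusted p = 0.0773) and Ift81 43.6 and 55.9 CPM (adjusted p = 0.0809). The camera adjusted p was 0.000249, and the adjusted p = 0.48 with an estimated correlation. Of 42 genes of the transition zone and basal body, 0 passed over all genes (11 at an unadjusted p below 0.05 in limma) and 8 were higher adjusted over the list alone (median 0.17), with Cep290 at 65.2 and 103.9 CPM (adjusted p = 0.0513), Cep83 at 61.7 and 86.5 CPM, Rpgrip1l at 56.6 and 82.6 CPM and Sclt1 at 44.4 and 59.8 CPM. That list had a camera adjusted p of 0.00411, an adjusted p = 0.56 with an estimated correlation, and 0.0798 without control replicate 3. The enzymes of tubulin glycylation and glutamylation did not rank apart (21 measured, median 0.18, camera adjusted p = 0.186), and 0 passed over all genes (10 at an unadjusted p below 0.05 in limma), with 6 higher and 2 lower adjusted over the list alone. Ttll3, which adds glycine to tubulin, measured 5.25 ± 1.38 and 8.88 ± 1.36 CPM (log2 change 0.67 ± 0.21, adjusted p = 0.124).

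Feedback targets of canonical Wnt signalling lay slightly lower. None of 24 measured genes passed over all genes tested (9 at an unadjusted p below 0.05 in limma), and 3 were lower adjusted over the list alone, Nkd1, Axin2 and Nkd2, each a feedback inhibitor of the pathway. Nkd1 measured 35.9 ± 3.29 CPM in control and 22.7 ± 1.29 CPM in mutant (log2 change -0.64 ± 0.11, adjusted p = 0.0513), Axin2 53.9 ± 6.86 and 37.1 ± 6.81 CPM (-0.53 ± 0.15, adjusted p = 0.104), Nkd2 23.3 and 15.7 CPM, and Myc 37.9 and 29.7 CPM. Lef1, another target, measured 14.6 ± 5.26 and 15.5 ± 5.76 CPM (adjusted p = 0.920). The list had a median log2 change of -0.15 and a camera adjusted p of 0.00569, and the adjusted p = 0.46 with an estimated correlation. Of 55 Wnt ligands, receptors and transducers, 0 passed over all genes (15 at an unadjusted p below 0.05 in limma) and 0 over the list alone (median -0.07). Fzd4 measured 77.0 and 51.1 CPM, Fzd2 88.2 and 59.9 CPM, Sfrp2 682.8 and 409.8 CPM, and Dvl3 79.0 and 63.8 CPM. Their camera adjusted p was 0.00652, an adjusted p = 0.56 with an estimated correlation, and 0.0760 without control replicate 2. The cadherin and catenin list did not rank apart (14 measured, camera adjusted p = 0.682), with 1 higher adjusted over the list alone and 0 over all genes (2 at an unadjusted p below 0.05 in limma).

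The Hedgehog, FGF, and BMP and TGF-beta lists ranked lower at the preset correlation. In the Hedgehog list (23 measured) 0 passed over all genes (5 at an unadjusted p below 0.05 in limma, near the share of the whole table, 4702 of 21938). Adjusted over the list alone 2 were lower, Shh at 18.4 ± 4.17 and 7.78 ± 1.90 CPM (adjusted p = 0.0613) and Gas1, a coreceptor, at 72.3 and 42.5 CPM (adjusted p = 0.0682). Cdon measured 118.4 and 91.9 CPM and Foxf2 46.6 and 24.8 CPM. The targets Gli1 (44.5 and 38.7 CPM, adjusted p = 0.529), Ptch1 (205.8 and 173.7 CPM, adjusted p = 0.483) and, named after its values were seen, Hhip (60.9 and 32.8 CPM, adjusted p = 0.170) did not pass over the list alone. The Hedgehog median was -0.23 and the camera adjusted p 0.000185, with an adjusted p = 0.48 with an estimated correlation. In the FGF list (20 measured, median -0.26) Fgfr4 fell over all genes, and 5 were lower and 1 higher adjusted over the list alone. The feedback inhibitors Spry1 (48.6 and 31.6 CPM, adjusted p = 0.0510) and Spry4 (34.7 and 20.8 CPM, adjusted p = 0.0552) were lower, and Fgfr2 was the 1 higher (183.5 and 261.0 CPM, adjusted p = 0.0933). The FGF list had a camera adjusted p of 2.95e-05, and an adjusted p = 0.46 with an estimated correlation. In the BMP and TGF-beta list (36 measured, median -0.13) 0 passed over all genes (8 at an unadjusted p below 0.05 in limma) and 1 was lower adjusted over the list alone. Tgfbi measured 115.7 and 78.7 CPM, Id3 31.7 and 24.4 CPM, and Nog 6.83 and 3.87 CPM. That list gave a camera adjusted p of 0.000353, and an adjusted p = 0.48 with an estimated correlation. The retinoic acid list (18 measured, camera adjusted p = 0.294) and the Notch list (16 measured, 0.121, and 0.0406 without control replicate 3) did not rank apart, and no gene of either passed over the list alone or over all genes (3 and 1 at an unadjusted p below 0.05 in limma).

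Among 35 palatal mesenchyme transcription factors, Osr2, the locus of the Cre allele, fell and 0 rose over all genes, and 5 were lower adjusted over the list alone (median -0.30). Mn1, a transcriptional regulator of palate growth, measured 184.9 ± 23.5 and 117.4 ± 13.1 CPM (adjusted p = 0.0571), Tbx2 42.4 and 28.9 CPM, and Hic1 45.6 and 24.1 CPM. The list had a camera adjusted p of 0.000261, and an adjusted p = 0.46 with an estimated correlation. Of 37 genes of the fibroblast extracellular matrix, 0 passed over all genes (14 at an unadjusted p below 0.05 in limma) and 1, Col26a1, was lower adjusted over the list alone (119.2 and 68.1 CPM, adjusted p = 0.0627; list median -0.32). Fbln1 measured 150.01 and 103.6 CPM and Col6a1 252.6 and 162.7 CPM, while Has1, a hyaluronan synthase, measured 13.4 and 21.7 CPM. The camera adjusted p was 1.05e-06, and the adjusted p = 0.56 with an estimated correlation.

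Skeletal lineages showed larger values in the mutant with wide spread. In the osteogenic list (22 measured, median 0.27) 0 passed over all genes (5 at an unadjusted p below 0.05 in limma) and 0 over the list alone. Ibsp, bone sialoprotein, measured 100.6 ± 113.5 and 364.2 ± 185.4 CPM (adjusted p = 0.119), Dmp1 2.90 and 10.7 CPM, Panx3 6.77 and 17.4 CPM, Mef2a 132.7 and 154.9 CPM, and Runx2, the master regulator of osteoblasts, 50.2 ± 0.40 and 61.6 ± 15.8 CPM (adjusted p = 0.380). Its camera adjusted p was 0.0255, an adjusted p = 0.60 with an estimated correlation, and 0.311, 0.186 and 0.0668 without control replicate 2, mutant replicate 5 and mutant replicate 6. In the chondrogenic list (25 measured, median 0.31) 0 passed over all genes (5 at an unadjusted p below 0.05 in limma) and 0 over the list alone. Sox5 measured 21.2 and 40.5 CPM, Sox6 80.2 and 117.6 CPM, Col11a2 39.0 and 76.2 CPM, Fgfr3 32.8 and 54.1 CPM, and Sox9 67.7 ± 12.4 and 81.6 ± 26.8 CPM (adjusted p = 0.599). Its camera adjusted p was 0.0340, an adjusted p = 0.65 with an estimated correlation, and 0.295, 0.463 and 0.214 without control replicate 2, control replicate 3 and mutant replicate 7. Tendon genes did not rank apart (14 measured, median -0.30, camera adjusted p = 0.0633), with 1, Tnc, lower adjusted over the list alone. They ranked lower without control replicate 2, control replicate 3 or mutant replicate 6 (0.0190, 0.00371 and 0.0302).

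Lists of blood, glial and neuronal cells, which a dissected palate can hold, ranked lower at the preset correlation. Of 17 erythroid genes 0 passed over all genes (12 at an unadjusted p below 0.05 in limma) and 10 were lower adjusted over the list alone (median -0.82). Hba-a1 measured 316.7 ± 144.7 and 77.1 ± 20.4 CPM (adjusted p = 0.0562), Hbb-y 134.3 and 45.1 CPM, Hbb-bt 399.7 and 153.8 CPM, and Sptb 29.8 and 16.3 CPM. Some globin genes, such as Hba-a1 and Hba-a2, are near-identical copies, so reads can be split between them. The list had a camera adjusted p of 3.30e-09, and an adjusted p = 0.48 with an estimated correlation. Macrophage and leukocyte genes (24 measured, median -0.25) passed 0 over all genes (5 at an unadjusted p below 0.05 in limma) and 0 over the list alone, with C1qb at 6.99 and 3.73 CPM, Ctss at 15.4 and 10.6 CPM, Laptm5 at 12.6 and 9.16 CPM and Coro1a at 9.93 and 6.67 CPM. They had a camera adjusted p of 0.000249, and an adjusted p = 0.54 with an estimated correlation. Among 17 Schwann cell and glia genes, Ngfr, a neurotrophin receptor of neural crest cells, fell over all genes and over the list alone (79.3 ± 5.03 to 48.1 ± 6.21 CPM, adjusted p = 0.0430), while Sox8 measured 14.3 and 8.28 CPM, Sox10 14.4 and 9.57 CPM and Mbp 20.7 and 28.4 CPM. The glial list (median -0.26) had a camera adjusted p of 0.0222, an adjusted p = 0.60 with an estimated correlation, and 0.101, 0.112 and 0.190 without control replicate 1, mutant replicate 6 and mutant replicate 7. Neuronal genes (25 measured, median -0.55) passed 0 over all genes (2 at an unadjusted p below 0.05 in limma) and 0 over the list alone, and Nefm measured 148.7 ± 93.3 and 66.7 ± 63.9 CPM, Nefl 116.3 ± 64.6 and 54.7 ± 54.8 CPM, Dcx 113.0 and 74.7 CPM and Stmn3 29.9 ± 8.87 and 16.4 ± 12.97 CPM. With 1 library left out the log2 change of Nefl lay between -2.13 and -0.89 and that of Stmn3 between -1.62 and -0.62, the lowest without mutant replicate 5. The neuronal list had a camera adjusted p of 0.00298, an adjusted p = 0.60 with an estimated correlation, and 0.0672 and 0.507 without control replicate 3 and mutant replicate 6.

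Epithelial genes lay higher. Of 44 measured, 0 passed over all genes (6 at an unadjusted p below 0.05 in limma) and 0 over the list alone (median 0.21). Krt15, a keratin of basal cells, measured 451.2 ± 71.3 and 686.6 ± 106.9 CPM (adjusted p = 0.0910), Krt18 72.2 and 105.7 CPM, Rab25 7.39 and 11.1 CPM, and Grhl2 57.5 and 93.3 CPM. The list had a camera adjusted p of 0.0182, an adjusted p = 0.67 with an estimated correlation, and 0.972 and 0.482 without control replicate 1 and mutant replicate 6. Of 16 markers of respiratory and nasal epithelium, 0 passed over all genes (2 at an unadjusted p below 0.05 in limma) and 2 were higher adjusted over the list alone (median 0.46), the mucin Muc16 at 40.4 ± 18.4 and 125.8 ± 75.6 CPM (adjusted p = 0.101) and Agr2 at 2.12 and 5.52 CPM. Foxa1 measured 66.0 and 96.4 CPM and Muc4 24.1 ± 10.8 and 53.7 ± 38.6 CPM. Without mutant replicate 7 their log2 changes went from 0.53 and 1.01 to 0.27 and 0.47. Its camera adjusted p was 0.0368, an adjusted p = 0.60 with an estimated correlation, and 0.0624, 0.286 and 0.2501 without control replicate 1, control replicate 3 and mutant replicate 7. Endothelial genes (25 measured, camera adjusted p = 0.219) did not rank apart, but did without control replicate 3 or mutant replicate 5 (0.00103 and 0.0310). Pituitary and ventral brain genes (7 measured, 0.339) did not, and of the melanocyte list 3 genes were measured, too few to test.

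**Figure D2:**
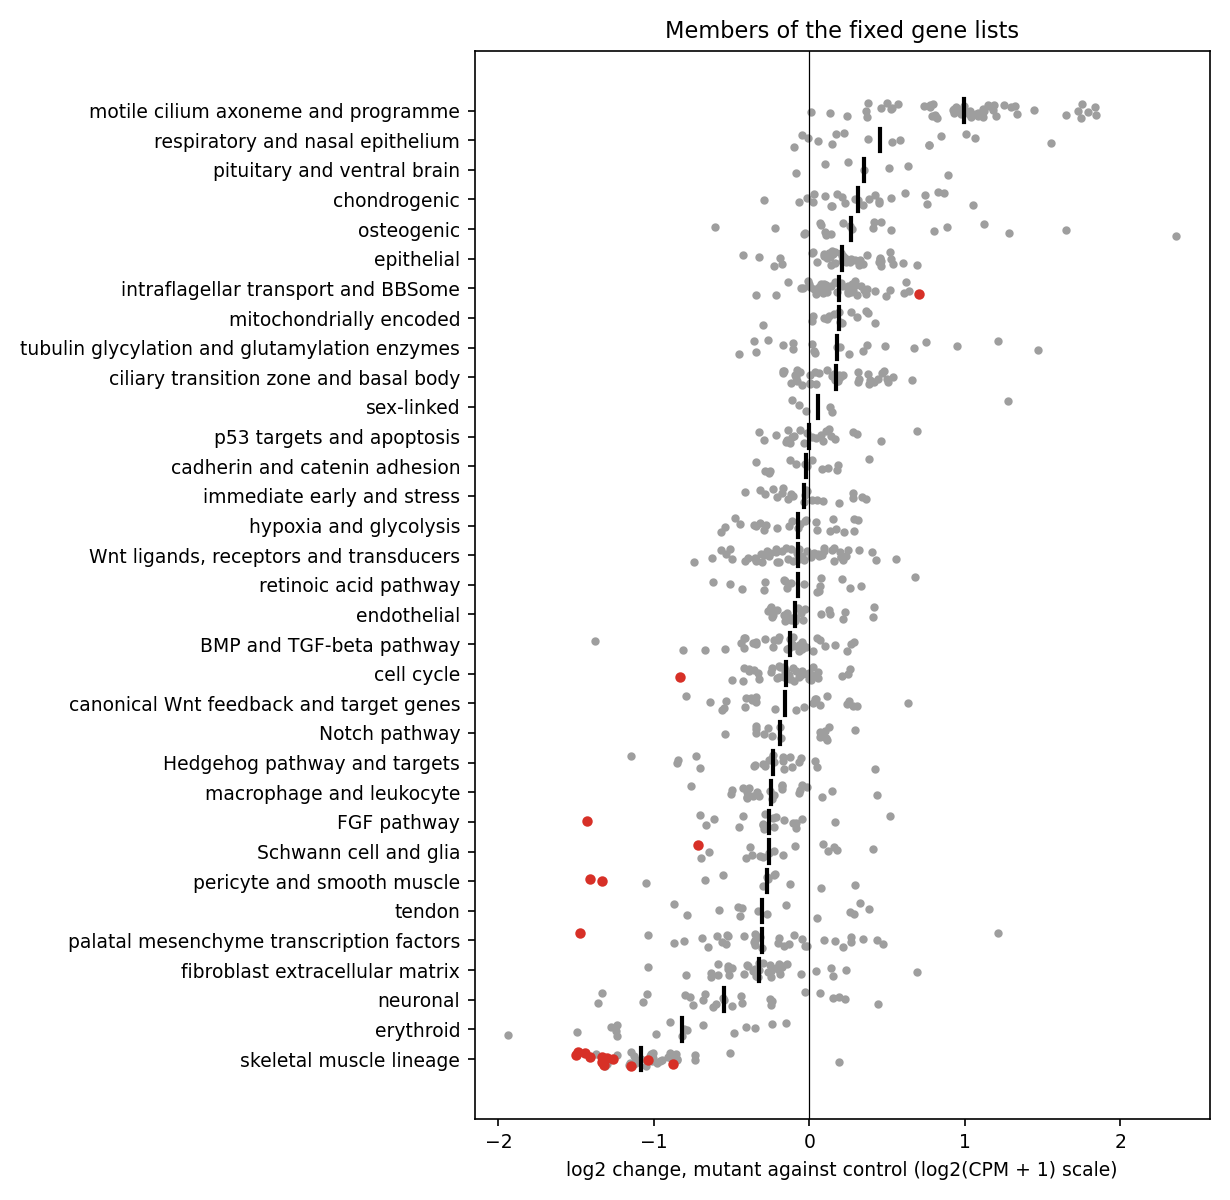
Log2 change of each measured member (points) of the gene lists with at least 5 measured genes, mutant against control on the log2(CPM + 1) scale, with the list's median as a black line and members that passed the threshold over all genes in red. The motile cilium list has a median of 0.99 and the skeletal muscle list one of -1.08.

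Lists of cell state were mixed. Among 39 cell cycle genes Ube2c, a ubiquitin-conjugating enzyme of mitosis, fell from 72.9 ± 3.88 to 40.9 ± 7.35 CPM (adjusted p = 0.0448), and 3 were lower adjusted over the list alone, Ube2c, Ccne1 (37.5 and 27.7 CPM) and Rrm2 (51.9 and 39.5 CPM), while Mcm5 measured 83.3 and 65.3 CPM. Their median was -0.15 and their camera adjusted p 0.000157, an adjusted p = 0.60 with an estimated correlation, and 0.0928 without mutant replicate 5. Hypoxia and glycolysis genes (25 measured, median -0.07) passed 0 over all genes (10 at an unadjusted p below 0.05 in limma), with 6 lower and 2 higher adjusted over the list alone. The members that were lower include the glycolytic enzymes Aldoa (243.3 and 178.0 CPM), Eno1 (68.6 and 45.8 CPM), Tpi1 (139.9 and 109.9 CPM) and Gpi1 (115.0 and 92.1 CPM), and the camera adjusted p was 0.0162, with an adjusted p = 0.48 with an estimated correlation. The p53 and apoptosis list (24 measured, median 0.00, mean 0.03, camera direction down, adjusted p = 0.904), the immediate early and stress list (22 measured, 0.307), the mitochondrially encoded list (15 measured, 0.142, and 0.0467, 0.00879 and 0.0352 without control replicate 1, control replicate 2 and mutant replicate 7) and the sex-linked list (6 measured, 0.549) did not rank apart, and of their members only Tsix, of the sex-linked list, was past the threshold over the list alone. Xist measured 1188 CPM in control replicate 3 and 2054 CPM in mutant replicate 7 and at most 17.3 CPM in the other libraries, where Ddx3y, of the Y chromosome, measured 69.7 to 98.8 CPM, so each group held 1 library with the female pattern.

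Non-coding transcripts inside or overlapping coding genes were higher in the mutant libraries. Among genes at or above the lower quartile of level, 869 non-coding genes inside an intron of a coding gene on the same strand had a median log2 change of 0.60 (95% bootstrap interval over genes 0.57 to 0.62), against 0.25 for 281 inside introns on the opposite strand, 0.32 (0.29 to 0.36) for 514 that overlap an exon or end of a coding gene, 0.01 (-0.02 to 0.03) for 763 non-coding genes over 10 kb from a coding gene and -0.02 for 13255 coding genes. Of the same-strand intronic genes, 14 rose and 0 fell past the threshold, and 512 were higher at an unadjusted p below 0.05. Malat1, a nuclear non-coding RNA, measured 9622 ± 815 CPM in control and 17020 ± 1590 CPM in mutant, named after its values were seen (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). This difference between the libraries lies along the genotype and goes with each gene group above.

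**Figure D3:**
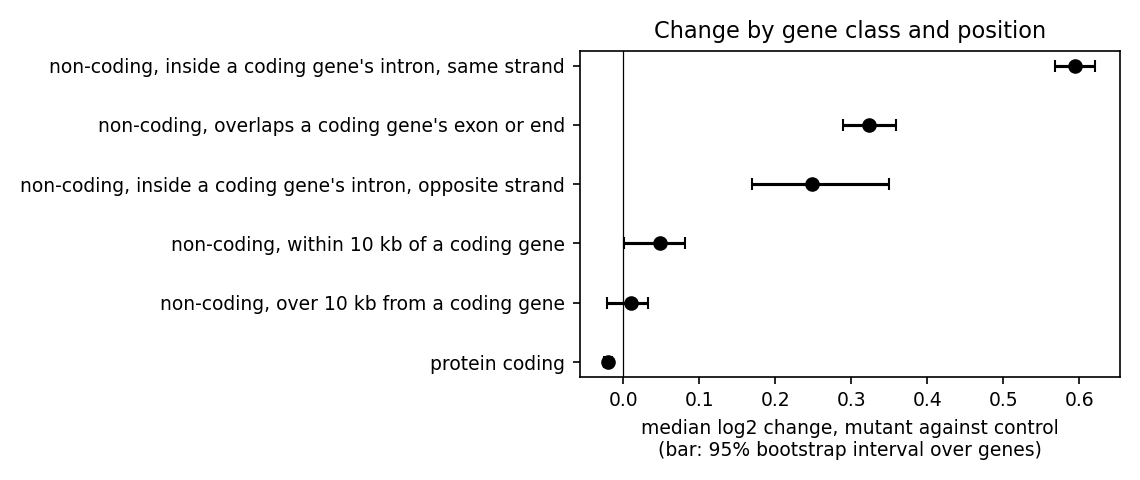
Median log2 change of coding genes and of non-coding genes by their position relative to coding genes, mutant against control, for genes at or above the lower quartile of level, with 95% bootstrap intervals over genes. Non-coding genes inside same-strand introns have a median of 0.60 and those over 10 kb from a coding gene one of 0.01.

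The second deposited table was the authors' filtered list of 2432 genes, whose values were identical to those of the full table. By the ratio of group means 1810 of them were higher and 622 lower in the mutant, 74.4% higher. The smallest ratio of group means in it was 1.5, and 2421 of its genes had an unadjusted p below 0.05 in limma. These genes were chosen by the study on these libraries, so their direction is not independent evidence. Of the 105 genes called here, 98 were in that list. In the full table, 2628 genes had both an unadjusted p below 0.05 and a ratio of at least 1.5.

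Because the Cre allele is inserted at Osr2, genes around it were compared with all others. Within 10 Mb of Osr2, 4 of 120 genes were called (3.33%), against 0.461% elsewhere (Fisher's exact test, two-sided, p = 0.00263), while within 5 Mb 0 of 76 were called (26.3% at an unadjusted p below 0.05 in limma, against 21.3% elsewhere). The 4 genes Gm49265, Gm49266, Gm49268 and Gm6330, named after their values were seen, lie in introns of 1 gene, Fbxl7, between 26672937 and 26746137 of chromosome 15. Counted once per host gene, 1 of 91 units was called (1.10%, against 0.524% elsewhere, Fisher's exact test, p = 0.382). Within 10 Mb of Ctnnb1, 1 of 142 genes was called, Xirp1 (Fisher's exact test, p = 0.498). No chromosome held more called genes than the others after adjustment, the lowest being chromosome 19 with 8 of 598 (Fisher's exact test, p = 0.00834, adjusted p = 0.175).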

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

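The covariate, voom, no trend and robust settings, fry, both criteria of the filtered list together and the test of 7 muscle regulators were chosen after seeing the data. The 105 genes called kept their direction in every refit, which is little evidence of stability since they were chosen on these same libraries. Their count moved with the setting. It was 0 at an FDR of 0.01 and 999 at 0.1 (622 higher, 377 lower), 98 with a fold of at least 1.5, 66 with a fold of at least 2 (23 higher), and 4702 at an unadjusted p below 0.05 (2931 higher, 1771 lower). Over genes at or above the median level 338 were called (173 and 165), and at or above the lower quartile 293 (155 and 138), since fewer genes were tested; the share higher went from 41.0% to 51.2% and 52.9%. Scaling to the median of genes above the median level gave 130 (66 higher, 50.8%) and shifted log2 changes by a median of 0.02. Leaving out 1 library gave 0 to 452 (0 to 254 higher, 0 to 198 lower). A prior variance without trend and sex as a covariate gave 0 (0 higher, 0 lower; 4516 and 4356 genes at an unadjusted p below 0.05 in limma), a robust prior 174 (86 and 88) and voom 106, of which 100 were shared. The cause was not tested, except that leaving out a library or adding a covariate lowers the residual degrees of freedom.

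Ctnnb1 stayed lower in all settings, from -0.30 to -0.19 with 1 library left out. Of 33 lists, 22 passed in the main test, 13 at a preset correlation of 0.05, 6 at 0.1 and 0 with an estimated one, and 19 to 21 with 1 library left out. Canonical Wnt targets had an adjusted p of 0.0534 at 0.05, 0.155 at 0.1 and 0.462 with an estimated correlation, while skeletal muscle (0.462) and motile cilium (0.512) lost their call with the estimated correlation alone. In fry no list passed, the smallest adjusted p being 0.153, with an unadjusted p of 0.0105 for skeletal muscle and 0.0553 for motile cilium. Lists whose share of called genes differed from the table numbered 2, and 5 with calls at an unadjusted p below 0.05, of which 4 held more and the endothelial list fewer (0 of 25, Fisher's exact test, adjusted p = 0.0433). The Hedgehog, BMP and TGF-beta, osteogenic, chondrogenic and macrophage lists did not differ from the table at that cut. The authors' 2432 genes compare with 4702 by p alone and 5125 by fold alone. Within 20 Mb of Osr2 2.61% of genes were called (Fisher's exact test, p = 0.00624).

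Some results that did not pass turned: Lef1 lay between -0.18 and 0.34 with 1 library left out, Gli1 between -0.35 and 0.00784, and Sox9 between -0.00048 and 0.49. Muscle regulators less other muscle genes went from -0.29 to 0.0735 with 7 regulators in place of 4. The p53 list changed direction over genes at or above the lower quartile (adjusted p = 0.918), and with 1 library left out its adjusted p was 0.473 to 0.947, that of the mitochondrial list 0.00879 to 0.744, and that of the sex-linked list 0.0780 to 0.947. Of 140 alternative values of the main results, 84 stayed the same and 50, all counts, moved by over 1.5 times. A further 5 were weaker, 1 was stronger and 0 turned direction. Of the 2092 other values, 1758 kept direction and call, 258 lost the call, 64 gained one and 12 turned direction. Centring z values leaves a test against other genes as it is and is void. The alternatives on counts and on an FDR column were not run, since neither was held here. No paired analysis was possible because the groups share no replicate number. A 1.5-fold change was found in 17.9% of simulated genes, all of equal variation, so small changes can be missed, and larger ones in genes that vary more.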

Other observations

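The tests of a smaller share of muscle cells and of nasal epithelium, the test of 7 muscle regulators, the comparison with host genes and the count of 1 unit per host near Osr2 were chosen only after the results were seen. For the first pair, the demand that the bootstrap interval of the difference leave out 0 was added once their values were known; without it the muscle test would count against a smaller share of muscle cells and the nasal test in favour of nasal epithelium. Within the list of tubulin glycylation and glutamylation, members moved both ways. Ttll6, a polyglutamylase, measured 2.00 and 7.03 CPM in control and mutant (log2 change 1.47 ± 0.39, adjusted p = 0.101), Ttll10, a polyglycylase, 3.08 and 8.67 CPM (1.22 ± 0.22, adjusted p = 0.0571), and Agbl2, a deglutamylase, 6.29 and 12.5 CPM (0.95 ± 0.29, adjusted p = 0.123). Tpgs1, a subunit of a polyglutamylase complex, measured 9.09 and 6.34 CPM. None passed over all genes in limma, and all 4 were past the threshold adjusted over the list alone; they were named after their values were seen.

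Non-coding transcripts were higher in the mutant, by 0.29 (median log2, 95% bootstrap interval 0.26 to 0.32) relative to coding genes. A regression on gene length, GC content and level left a difference of 0.159 (0.143 to 0.175). As fitted, these traits thus do not account for all of it. Coding and non-coding genes were fitted together, so the regression can also take up part of the difference between them. How much the traits account for is therefore open. Same-strand intronic genes exceeded distant ones by 0.585 (0.549 to 0.624), or 0.299 after the regression. Reads from genomic DNA would add to both. The intronic genes lay lower in control (median log2 2.00 against 3.31), where added reads move log2 more. The regression includes level, however, and the 0.299 it left had an interval of 0.256 to 0.344. The distant genes changed by a median of 0.01 (-0.02 to 0.03). These values argue against genomic DNA as the whole cause for these genes. A difference above 0 is what more unspliced RNA in the mutant libraries needs. Intronic genes also exceeded their own host genes by 0.54 while the hosts changed by a median of 0.06, so more unspliced or nuclear RNA is a candidate explanation. Whether it comes from the genotype or from the handling of the pieces is open, since the design joins both.

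Skeletal muscle genes were lower by a median of -1.08, and gene length, intron length, GC content and level are argued against as the whole cause, since the median was -1.02 (-1.10 to -0.95) after the regression. A smaller share of muscle cells in the mutant pieces would lower regulators and other muscle genes alike: the 4 regulators Pax7, Myf5, Myod1 and Myog had a median of -1.38 and 36 other members one of -1.09 (permutation p over genes = 0.0123, 100000 draws), but the bootstrap interval of the difference, -0.46 to 0.07, held 0. With the regulators Pax3, Myf6 and Mef2c, left out of both groups, the median of 7 was -1.02 (permutation p = 0.666), with an interval of the difference of -0.40 to 0.63. A smaller share and a lower expression per cell cannot be told apart here, and the piece of tissue taken may also differ, as may the genotype's own effect on muscle. A count of Pax7 and Myog cells in sections would bear on this hypothesis.

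Motile cilium genes were higher by a median of 0.99, and after the regression by 1.01 (0.85 to 1.06), which argues against gene length, intron length, GC content and level as the cause. More ciliated nasal epithelium in the mutant pieces is a candidate explanation: the respiratory and nasal list, none of which is in the motile cilium list, lay 0.414 (0.070 to 0.729) above all genes, but exceeded the epithelial list by 0.25 with an interval of -0.09 to 0.60. Abundant genes of that list include Cyp2f2 (82.9 and 138.8 CPM in control and mutant), Muc16 (40.4 and 125.8 CPM) and Foxa1 (66.0 and 96.4 CPM). The share of ciliated cells and the expression per cell cannot be told apart, and an effect of the genotype on cilia stays open and untested.

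The splits of the 6 libraries into 3 and 3 are too few, 10 with the real one, for a share under 0.05. The real split called 105 genes and the highest other split 3, so 1 split reached the real value. For the lists the real split took 22 past the threshold at the preset correlation and the other splits 12 to 17, again 1 split at the real value. With the estimated correlation each split took 0. Lists thus often passed at the preset correlation under groupings that mix control and mutant. Within 10 Mb of Osr2 the share of called genes was higher than elsewhere (Fisher's exact test p = 0.00263), and counting intronic genes once per host gene left 1 of 91 units (p = 0.382).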
